A study of Mus musculus with 28 samples.

How the data were processed

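Bulk RNA-seq libraries of mouse adipose tissue were compared between control mice and mice with an adipose knockout of Fgf13. The 28 libraries came from 5 depot data sets. Inducible knockout was studied in epididymal (ieWAT) and subcutaneous (isWAT) white fat, constitutive knockout in subcutaneous white fat (sWAT) and brown fat (BAT), and a further epididymal set (eWAT) has no knockout type or diet in the series text. The mice of the other 4 sets were obese after 20 weeks on a high fat diet. Each depot had 3 control libraries, and there were 3 knockout libraries in ieWAT, sWAT and eWAT and 2 in isWAT and BAT. The labels do not say that the libraries of a group came from separate animals or whether depots shared animals, so each p measures the spread between these samples.

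The tools Salmon, FastQC, MultiQC and DESeq2 1.38.3 were used by the authors, per the submitters' processing notes. Those notes give no role for each tool, and the aligner, genome build and annotation release are not given in the sources used here. Of 7 deposited tables, the 5 depot tables are all named as FPKM. The values of the ieWAT, isWAT, sWAT and BAT tables are CPM as deposited, reads scaled to the library total: each column has the same sum, 1000000, and 100% of values were whole multiples of the value of 1 read within a tolerance of 0.01 reads, with no division by gene length. The deposited eWAT table holds FPKM, with column sums that differ between samples. A further deposited table, named as raw counts, holds TPM for the same 6 eWAT samples, and its columns correlated with one another at 0.54 to 0.92, against at least 0.94 between columns of the main eWAT table. It was used only as an added alternative. The last deposited table equals that TPM table times 1 factor per column, from 2.12 to 45.11, and was not used.

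Whole reads were recovered from the CPM tables. Totals ran from 29857189 to 43624353 reads per library in ieWAT, 37700750 to 48812592 in isWAT, 13490948 to 21241811 in sWAT and 14951333 to 21246286 in BAT. One read was worth 0.0205 to 0.0741 CPM. The eWAT tables give no read totals, and the depth relative to the first control library was estimated at 0.64 to 1.0 from the most common ratio of low values. Gene symbols came from GENCODE M21 (GRCm38) by Ensembl identifier and covered 92.0% of identifiers (96.0% in ieWAT). Unmatched identifiers held at most 1.45% of a library's total.

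Each depot was fitted alone, because the depots were deposited as separate tables with separate normalisation. The plan made before the data were examined was edgeR for counts, or limma on log2(FPKM + 1) without counts. Since the tables held CPM or FPKM, limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust options, two-sided) was applied to log2(value + 1), and the rule for FPKM was also used for CPM: genes with a value of at least 1 in as many libraries as the smaller group were kept. P values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. A gene list was tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a depot, for lists with at least 3 genes tested. The 44 lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Fgf13 was also tested with an exact two-sided permutation test, whose smallest p is 0.1 with these group sizes.

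Genes named in the text are Fgf13; up to 10 higher and 10 lower genes per depot with the largest fold change past the threshold, without overlap of the groups, with a mean of at least 1 in the higher group and with a symbol that is not a bare model name; up to 4 members with the smallest p of each list past the threshold; Ucp1, Adipoq, Lep, Pparg, Slc2a4, Cav1, Cavin1 and Fasn as values; and up to 10 genes called in most depots. Where under 5 genes passed in a depot, the 10 with the smallest unadjusted p are given as values. Other names were chosen after their values were seen, and this is said where they occur.

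The tests were tried on simulated data with 200 genes changed in each depot. Of 100 genes changed 2-fold, limma called 83 in ieWAT, 96 in isWAT, 90 in sWAT, 81 in BAT and 91 in eWAT. Unchanged genes called numbered 18, 21, 17, 10 and 10 in the same order. On reads simulated for ieWAT, isWAT, sWAT and BAT, edgeR called 57, 91, 83 and 41 of the 100, and DESeq2 83, 93, 93 and 59. Unchanged genes called there numbered 15, 34, 11 and 19 with edgeR and 61, 58, 44 and 58 with DESeq2. Camera found a list moved by 0.5 (log2) and called 0 other lists in each depot. Genes were simulated independently of one another, so this does not test calls from genes that move together. The changed genes were not drawn from those with low control values.

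Alternatives were other scalings, other filters on low values, pseudocounts of 0.1 and 0.5, eBayes without its options, array weights, the replicate number as a block, leaving out each library, other thresholds, camera with an estimated correlation and limma's fry. Alternatives added after the data had been examined were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, the second eWAT table, and sWAT fits that allow for muscle RNA. No test was made between depot tables; shared calls were counted against n1 × n2 / N with a one-sided Fisher's exact test. Pseudogenes were compared with other annotated transcripts by shared words of 31 bases.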

Results

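Adipose tissue of mice was profiled by RNA-seq to find genes that respond to loss of Fgf13, a member of the fibroblast growth factor family that is not secreted. Of the 28 libraries, 15 were control and 13 knockout. They covered 2 inducible knockout sets (ieWAT with 3 control and 3 knockout libraries, isWAT with 3 and 2), 2 constitutive sets (sWAT with 3 and 3, BAT with 3 and 2) and an eWAT set of 3 and 3 whose knockout type and diet are not stated. The mice of the other 4 sets were obese, on a high fat diet. Libraries held 29857189 to 43624353 reads in ieWAT, 37700750 to 48812592 in isWAT, 13490948 to 21241811 in sWAT and 14951333 to 21246286 in BAT. For eWAT the read totals are unknown. Values are means ± SD in CPM (reads scaled to the library total), or in FPKM for eWAT, and changes are knockout minus control on the log2(value + 1) scale from limma with their standard error (SE).

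Fgf13 was read first, as a check of the labels. In ieWAT it averaged 44.3 ± 6.26 CPM in control (n = 3) and 27.1 ± 5.61 CPM in knockout libraries (n = 3), and in isWAT 60.3 ± 8.18 CPM (n = 3) and 33.3 ± 2.83 CPM (n = 2). In sWAT the means were 110 ± 3.63 CPM and 63.2 ± 20.496 CPM (n = 3 each). In BAT they were 9.07 ± 7.62 CPM (n = 3) and 1.06 ± 1.15 CPM (n = 2). Each knockout library of these 4 sets lay below each control library, with knockout means 38.9%, 44.8%, 42.3% and 88.3% lower. In BAT the 5 libraries had the same order by Fgf13 as by their extracellular matrix list (6.443, 5.716 and 7.024 in control, 5.033 and 5.306 in knockout libraries) and their fibroblast and progenitor list, so the BAT value goes with these lists and is weaker as a check. The log2 changes were -0.70 (SE 0.17), -0.83 (SE 0.12), -0.83 (SE 0.22) and -2.13 (SE 0.77). None passed Benjamini-Hochberg adjustment over all genes with limma (adjusted p = 1.00, 0.179, 0.447 and 0.251). The exact two-sided permutation p was 0.1, 0.1, 0.1 and 0.2, and 0.1 is the smallest these group sizes allow. In eWAT, Fgf13 was not lower: it averaged 20.3 ± 7.39 FPKM in control and 22.6 ± 4.76 FPKM in the libraries labelled knockout (n = 3 each, log2 change 0.19, SE 0.28, limma adjusted p = 0.677). The eWAT groups overlapped (exact permutation p = 0.7), and without the third control library the change was -0.09. Directions in eWAT therefore rest on the labels and not on a lower Fgf13.

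**Figure D1:**
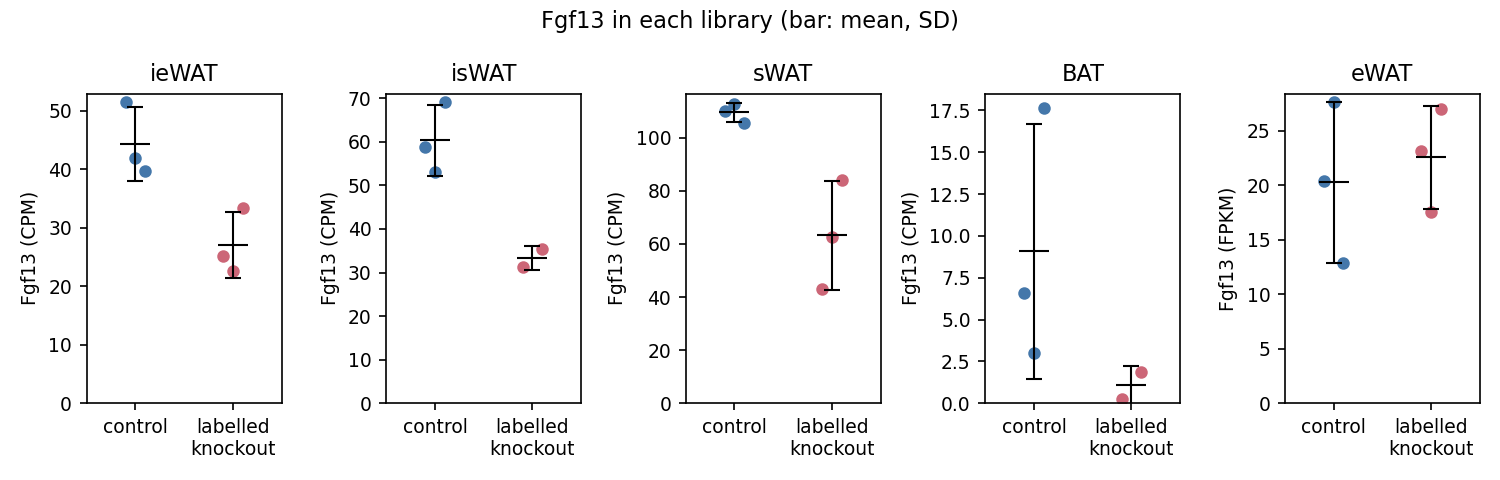
Fgf13 in each library (points; CPM, or FPKM for eWAT on the vertical axis) by group, with the mean and SD as bars. Knockout libraries lie below control libraries in ieWAT, isWAT, sWAT and BAT, and the eWAT groups overlap with means of 20.3 and 22.6 FPKM.

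The ieWAT comparison asked what inducible knockout changes in epididymal fat. No gene passed the test, so the values below describe these libraries only. Several transcripts of lymphocytes were among the genes with the smallest p. Ighm, the heavy chain of IgM, averaged 1698 ± 480 CPM in control and 4330 ± 1068 CPM in knockout libraries (n = 3 each, log2 change 1.36, SE 0.28). Lck, a kinase of T cell receptor signalling, averaged 4.85 ± 2.22 and 12.6 ± 2.43 CPM (1.27, SE 0.27), and the T cell receptor chain Trac 4.52 ± 1.05 and 9.26 ± 1.48 CPM. The regulatory T cell receptors Tnfrsf4 (0.686 to 2.28 CPM) and Tnfrsf18 (1.09 to 3.27 CPM) and the T cell kinase Zap70 (2.13 to 4.80 CPM) were among the 10 genes with the smallest p. So were the secreted Wnt enhancer Rspo1 (10 to 19.4 CPM), the matrix proteins Spon1 (27.8 to 49.1 CPM) and Mgp (222 to 333 CPM), the nuclease Dnase1l3 and 2 immunoglobulin kappa genes, Igkv4-50 and Igkv4-91. The fatty acid desaturase Scd2 averaged 434 ± 23.9 CPM in control and 267 ± 9.05 CPM in knockout libraries (-0.70, SE 0.11). Collagen VI chains had lower values: Col6a2 averaged 1169.8 ± 127 and 833 ± 75.7 CPM, and Col6a1 965 ± 99.5 and 717 ± 73.2 CPM. Adipoq averaged 1425 ± 103 and 1580.3 ± 374 CPM, Lep 2548 ± 299 and 2450.4 ± 324 CPM, Pparg 132 ± 13.9 and 125 ± 9.92 CPM, Slc2a4 77.9 ± 9.90 and 80.8 ± 26.0 CPM, and Fasn 1804 ± 468 and 1398 ± 205 CPM. The groups overlapped for these 5 adipocyte genes, and also for Cav1, Cavin1 and Ucp1. No gene passed with limma and Benjamini-Hochberg adjustment (0 of 14749; smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 386 genes, 295 higher and 91 lower. Without any effect that threshold would let through a share of 0.05 of the genes tested, and 386 of 14749 is below it. edgeR on the recovered reads called 0 and DESeq2 32, and limma called 1 without the first control or the third knockout library. The groups did not overlap for 5.11% of genes, where chance gives 10%.

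Among 43 lists tested in ieWAT, 14 passed with limma's camera, 6 higher and 8 lower. The T and NK cell list averaged 2.09 ± 0.40 in control and 2.89 ± 0.21 in knockout libraries (n = 3 each, log2 scale, adjusted p = 4.08e-23). Of its 16 members 0 passed over all genes, and 11 were higher adjusted over the list alone (adjusted p = 0.577 with an estimated correlation). The B cell and lymph node list averaged 3.25 ± 1.09 and 4.61 ± 0.46 (camera adjusted p = 2.19e-14), with overlap, since the first control library stood at 4.496 and the second knockout library at 4.074, and with 0 of 15 members past over all genes and 1 adjusted over the list alone (adjusted p = 0.795 with an estimated correlation). Extracellular matrix genes averaged 8.84 ± 0.11 and 8.54 ± 0.14 (camera adjusted p = 9.46e-16), and 0 of 27 passed over all genes or adjusted over the list alone (adjusted p = 0.561 with an estimated correlation). The interferon response list was higher by 0.25 (2.47e-07) and lipogenesis lower by 0.17 (camera adjusted p = 1.36e-04; 1 of 16 members lower adjusted over the list alone); both had adjusted p = 0.939 with an estimated correlation. Mesothelial, inflammatory cytokine and ribosomal protein lists were also higher, and heat shock, cell cycle, fibroblast and progenitor, neutrophil and mast cell, macrophage, and erythroid and platelet lists lower. For these 9 lists camera's adjusted p ran from 0.000491 to 0.0421, and 0 of their members passed over all genes or adjusted over the list alone. The groups overlapped for 11 of the 14 list means, and for 11 lists leaving out 1 library shrank the change 1.5 times or more, or reversed it. Lipogenesis went to -0.0697 without the third control library (adjusted p = 0.0659) and to -0.0711 without the third knockout library (0.145), the interferon response list to 0.154 without the second knockout library, and the macrophage and cell cycle lists to 0.1039 and 0.0329 without the second knockout library. Of the 14 lists, 5 passed without each library in turn (T and NK cell, B cell, extracellular matrix, interferon response and heat shock). No ieWAT list passed with camera at an estimated correlation (smallest adjusted p = 0.561) or with fry, against 14 with the preset correlation.

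In isWAT the question was the same for inducible knockout in subcutaneous fat. Esr1, the estrogen receptor alpha gene, rose from 10.8 ± 0.963 CPM (n = 3) to 29.7 ± 1.16 CPM (n = 2; log2 change 1.379, SE 0.11, limma adjusted p = 0.0390). It was the only gene past the threshold by limma. The next by p were given as values: the potassium channel Kcna5 averaged 48.5 ± 2.38 and 24.8 ± 2.44 CPM, the clock gene Per1 144 ± 2.51 and 82.4 ± 12.8 CPM, the neurotrophin receptor Ntrk3 12.1 ± 2.94 and 3.42 ± 0.525 CPM, and the ribosomal protein paralogue Rpl39l 2.88 ± 1.36 and 13.8 ± 1.501 CPM. Fam107a, Sdc4, Sik1, Ceacam1 and Jade2 had lower values in the knockout libraries, with log2 changes of -1.32, -0.83, -0.65, -0.66 and -0.76. Adipoq averaged 2313 ± 20.8 and 2768 ± 22.8 CPM (0.26, SE 0.08, limma adjusted p = 0.319), Lep 4395 ± 445 and 3642 ± 117 CPM and Cav1 1970.4 ± 38.8 and 2180.1 ± 63.4 CPM. The groups overlapped for Pparg, Slc2a4, Fasn, Cavin1 and Ucp1. Of 14258 genes, limma with Benjamini-Hochberg adjustment called 1. Without adjustment (p under 0.05) 567 genes were higher and 1302 lower, and DESeq2 on the recovered reads called 245. The limma count was 0 without the first control, the third control or the second knockout library, 12 without the second control and 6 without the first knockout library. The groups did not overlap for 31.6% of genes, where chance gives 20%.

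Of 41 lists in isWAT, 12 passed with limma's camera, 9 higher and 3 lower. Nuclear genes of oxidative phosphorylation averaged 6.85 ± 0.10 (n = 3) and 7.03 ± 0.19 (n = 2; camera adjusted p = 2.96e-12, but adjusted p = 0.681 with an estimated correlation, as for each of the 12), with Atp5l at 112 ± 10.8 and 144 ± 9.20 CPM. The mitochondrially encoded list was higher by 0.29 (4.18e-05), with mt-Atp8 at 159 ± 20.7 and 286 ± 78.7 CPM and 1 of 13 members past adjusted over the list alone. The lipid-associated macrophage list averaged 7.73 ± 0.26 and 8.12 ± 0.01 (camera adjusted p = 3.40e-06), with the lectin Lgals3 at 384 ± 66.3 and 509 ± 13.7 CPM. Ribosomal protein, interferon response, branched-chain amino acid catabolism, fatty acid oxidation, Schwann cell and nerve, and citric acid cycle lists were also higher (camera adjusted p from 7.63e-10 to 0.00754). Endothelial genes averaged 7.50 ± 0.09 and 7.27 ± 0.03 (3.09e-04), and 3 of 19 were lower adjusted over the list alone, with the receptors Flt1 at 196 ± 17.1 and 141 ± 10.4 CPM and Tek at 94.7 ± 5.53 and 69.9 ± 3.57 CPM. Immediate early genes were lower by 0.26 (camera adjusted p = 0.00269), and 6 of 17 were lower and 1 higher adjusted over the list alone, with Zfp36 at 90.3 ± 3.42 and 62.9 ± 0.863 CPM and Dusp1 at 69.5 ± 4.02 and 42.2 ± 7.23 CPM. Extracellular matrix genes were lower by 0.22 (3.09e-04). The first knockout library carried much of this. The nuclear oxidative phosphorylation list stood at 7.161 in it and at 6.897 in the second, inside the control range of 6.795 to 6.968, and without the first its change was 0.0428 (camera adjusted p = 0.0363). The mitochondrially encoded list (10.193 and 9.789, control up to 9.872) and the interferon response list (4.849 and 4.37, control 4.361 to 4.398) had the same form, with changes of 0.0874 and -0.0118 without it, and neither passed then. Nor did the extracellular matrix (-0.0974, adjusted p = 0.284), fatty acid oxidation (0.0231), citric acid cycle (0.0099) and branched-chain amino acid lists (0.0676). For 9 of the 12 lists leaving out 1 library shrank the change 1.5 times or more, among them the lipid-associated macrophage list (0.26 without the first control library) and the Schwann cell list (0.233 without the second knockout library). Of the 12 lists 6 passed without the first knockout library, and 5 without each library in turn. Over all genes 0 members of these 12 lists passed. With an estimated correlation 0 of the 12 passed, and fry called 0 lists.

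The sWAT comparison concerned constitutive knockout in subcutaneous fat. Bckdhb, a subunit of the dehydrogenase that breaks down branched-chain amino acids, rose from 48.7 ± 3.24 to 88.5 ± 5.19 CPM (n = 3 each; log2 change 0.85, SE 0.08, limma adjusted p = 0.0229). The processed pseudogene Gm7049 rose from 0.203 ± 0.0545 to 24.7 ± 8.43 CPM (4.36, SE 0.25, limma adjusted p = 0.00265). The processed pseudogene Gm11868 was listed at 0 in each control library and rose to 2.62 ± 0.126 CPM (limma adjusted p = 0.0166). Of their 31-base words, Gm7049 shares 65.3% with Me1 and Gm11868 57.9% with Cyb5r4, so reads of either pseudogene are uncertain. Further values among the 10 smallest p were Smpd3, a neutral sphingomyelinase that makes ceramide (11.2 ± 0.387 and 21.0 ± 2.39 CPM, 0.85, SE 0.11, limma adjusted p = 0.107), the glutathione transferase Gsta4 (9.10 ± 2.50 and 34.4 ± 9.41 CPM), the fatty acid hydroxylase Cyp4b1 (142 ± 7.54 and 97.5 ± 5.01 CPM), the collagen lysyl hydroxylase Plod2 (19.8 ± 1.26 and 9.54 ± 2.06 CPM) and Morf4l1-ps1 (0.549 ± 0.951 and 13.0 ± 0.183 CPM). Zxda averaged 1.65 CPM in control and was listed at 0 in knockout libraries, and Gm13772 was listed at 0 in control and averaged 1.69 CPM. The groups overlapped for Adipoq (2931 ± 194 and 2821 ± 327 CPM), Lep (4460.3 ± 204 and 5838 ± 1495 CPM), Fasn (1850.4 ± 318 and 1880.3 ± 335 CPM), Pparg, Slc2a4, Cav1 and Ucp1, and Cavin1 averaged 1712 ± 8.18 and 1604 ± 69.7 CPM. With limma and Benjamini-Hochberg adjustment 3 of 13816 genes passed. An unadjusted p under 0.05 was found for 267 higher and 1067 lower genes, and DESeq2 on the recovered reads called 85. The limma count was 120 without the first knockout library, 78 without the second, and 1 without the third or without the second control library. The groups did not overlap for 16.1% of genes, where chance gives 10%.

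In sWAT 11 of 41 lists passed with limma's camera, 4 higher and 7 lower. Mitochondrially encoded genes averaged 10.69 ± 0.02 in control and 11.11 ± 0.27 in knockout libraries (n = 3 each, camera adjusted p = 4.25e-12, but adjusted p = 0.778 with an estimated correlation, as for each of the 11), and 6 of 13 were higher adjusted over the list alone, with mt-Co2 at 4001 ± 529 and 6245 ± 880 CPM. Nuclear oxidative phosphorylation genes were higher by 0.05 (1.85e-06). Skeletal muscle genes moved with them: the list averaged 3.06 ± 0.08 and 5.05 ± 1.93 (camera adjusted p = 1.47e-05), at 2.82 in the first knockout library and 6.06 and 6.26 in the other two, with Acta1 at 19.9 ± 5.95 and 344 ± 284 CPM. The branched-chain amino acid list was higher by 0.17 (2.25e-05), with Bckdhb as 1 of 18 members past over all genes and adjusted over the list alone. Endothelial genes averaged 6.81 ± 0.01 and 6.55 ± 0.16 (camera adjusted p = 2.57e-05), and 9 of 19 were lower adjusted over the list alone, with Pecam1 at 389 ± 6.71 and 298 ± 24.1 CPM and Eng at 202 ± 1.71 and 151 ± 15.8 CPM. With the muscle list's mean as a covariate 40.0% of this change was left (-0.105, adjusted p = 0.401), and of the 11 lists 4 still passed. Lipid-associated macrophage genes averaged 8.17 ± 0.09 and 7.59 ± 0.52 (7.15e-04), with Gpnmb at 260 ± 35.1 and 135 ± 68.6 CPM and Lgals3 at 530 ± 9.30 and 344 ± 146 CPM. Interferon response genes were lower by 0.22 (9.37e-04), and 5 of 20 were lower adjusted over the list alone, with Irf7 at 38.3 ± 1.92 and 28.3 ± 3.03 CPM. Cell cycle, T and NK cell, B cell and lymph node, and unfolded protein response lists were also lower (camera adjusted p from 0.00947 to 0.0147). The third control library stands apart in the lymphocyte lists. The T and NK cell list was 2.17, 2.018 and 3.665 in control and 1.79, 2.154 and 2.078 in knockout libraries, so the groups overlap, and without the third control library its change of -0.61 was -0.087 (camera adjusted p = 0.996). The B cell list was 3.301, 2.471 and 5.054 against 2.55, 2.498 and 1.946, also with overlap, and went from -1.28 to -0.555 (camera adjusted p = 0.0440). Without the first knockout library the lipid-associated macrophage change of -0.579 was -0.289 (list means of 7.007, 8.02 and 7.732 in knockout libraries) and the branched-chain amino acid change of 0.169 was 0.0879 (6.943, 6.657 and 6.741, control up to 6.729). The interferon response list went to -0.1385 without the third knockout library (adjusted p = 0.111), the cell cycle list to -0.0919 without the first control library (0.382) and nuclear oxidative phosphorylation to 0.0289 without the third control library. Without each library in turn 7 of the 11 lists passed. Apart from Bckdhb, 0 members of the 11 lists passed over all genes. With an estimated correlation 0 lists passed, and fry called 0.

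In BAT, constitutive knockout was compared in brown fat. Gm7049 rose from 0.120 ± 0.118 CPM (n = 3) to 13.9 ± 4.08 CPM (n = 2; log2 change 3.71, SE 0.24, limma adjusted p = 0.0351) and was the only gene past the threshold by limma. Gm11868 and Morf4l1-ps1 were listed at 0 in control libraries and averaged 2.74 ± 0.660 and 5.09 ± 2.46 CPM in knockout libraries (limma adjusted p = 0.136 each). The fatty acid activating enzyme Acsl5 averaged 89.5 ± 6.06 and 183 ± 12.7 CPM (1.02, SE 0.11), and fatty acid synthase, Fasn, 2900.2 ± 1624 and 9326 ± 2413 CPM (1.80, SE 0.48, limma adjusted p = 0.237). The stress hormone Gdf15 averaged 10.005 ± 2.63 and 1.18 ± 0.157 CPM (-2.31, SE 0.24, limma adjusted p = 0.136), and the matricellular protein Ccn2 14.4 ± 2.47 and 4.53 ± 0.312 CPM. Eya2 had lower and Tgtp1, Ube2ql1 and Myo5b higher values, with log2 changes of -1.83, 2.32, 2.34 and 1.21. The glucose transporter Slc2a4 averaged 221 ± 44.1 and 346 ± 26.5 CPM (0.66, SE 0.18, limma adjusted p = 0.237). Ucp1, the uncoupling protein of brown fat, averaged 5992 ± 1126 and 5772 ± 1162 CPM (-0.05, SE 0.21), with overlapping groups. Lep averaged 733 ± 465 and 248 ± 44.0 CPM, Cav1 1054 ± 189 and 767 ± 26.0 CPM, and the groups overlapped for Adipoq, Pparg and Cavin1. Of 13253 genes limma with Benjamini-Hochberg adjustment called 1. At an unadjusted p under 0.05 there were 307 higher and 2233 lower genes, and on the recovered reads edgeR called 0 and DESeq2 691. The limma count was 2201 without the second control library and 0 without any 1 of the other 4. The median change of all genes was -0.18, against 0.06 after each library was centred on its median, which gave 7 higher and 2 lower calls. The groups did not overlap for 44.5% of genes, where chance gives 20%.

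In BAT 24 of 41 lists passed with limma's camera at the preset correlation, 12 higher and 12 lower, and 0 with an estimated correlation. Lipogenesis genes averaged 8.21 ± 0.23 (n = 3) and 8.87 ± 0.15 (n = 2; camera adjusted p = 4.58e-13), and 10 of 16 were higher and 1 lower adjusted over the list alone, with Elovl6 at 172 ± 42.6 and 378 ± 42.3 CPM, Acacb at 315 ± 45.8 and 619 ± 117 CPM and the carbohydrate response factor Mlxipl at 73.2 ± 10.6 and 135 ± 6.14 CPM. Nuclear oxidative phosphorylation genes averaged 8.504 ± 0.07 and 8.69 ± 0.12 (6.93e-28), citric acid cycle genes were higher by 0.23 (2.25e-10) with Pdha1 at 908 ± 113 and 1391 ± 154 CPM, and glycolysis genes by 0.28 (4.85e-08). These 4 lists had adjusted p = 0.576 with an estimated correlation. Macrophage genes averaged 4.81 ± 0.90 and 2.88 ± 0.00 (camera adjusted p = 2.90e-06), and 15 of 18 were lower adjusted over the list alone (adjusted p = 0.703 with an estimated correlation), with Cd68 at 48.0 ± 32.0 and 5.38 ± 0.815 CPM. In the lipid-associated macrophage list (6.49 ± 0.82 and 4.86 ± 0.07, 6.03e-04) Trem2 averaged 18.6 ± 14.9 and 0.765 ± 0.136 CPM and Lgals3 135 ± 103 and 10.2 ± 0.350 CPM. Interferon response genes were lower by 0.78 (camera adjusted p = 4.85e-08), 16 of 19 adjusted over the list alone, and extracellular matrix genes by 1.22 (2.36e-07), 11 of 27 adjusted over the list alone; with an estimated correlation their adjusted p was 0.576 and 0.703. The unfolded protein response (9 of 21), cell cycle (8 of 17), fibroblast and progenitor (3 of 15) and inflammatory cytokine (2 of 12) lists also had lower members adjusted over the list alone. The BAT libraries had the same order by the unfolded protein response and interferon response lists as by the extracellular matrix list. Cell cycle and inflammatory cytokine lists ordered them as the macrophage list did. These calls are therefore not set apart from the cell types that were lower there. Skeletal muscle genes passed as higher (8.28e-04), at 4.69, 6.13 and 1.31 in the control and 0.91 and 8.27 in the knockout libraries, so that 1 knockout library held the most and the other the least. Without the second knockout library the list passed as lower instead (-3.14, adjusted p = 0.0275). That library also had the higher nuclear oxidative phosphorylation mean (8.773, against 8.605 in the first), and without it the change of that list went from 0.185 to 0.1012 and still passed. Fatty acid oxidation, branched-chain amino acid, thermogenic, mitochondrially encoded, heat shock and triglyceride synthesis lists were also higher, and ribosomal protein, dendritic cell and MHC II, and T and NK cell lists lower (camera adjusted p from 4.76e-07 to 0.0343). Leaving out 1 library shrank 8 of the 24 changes 1.5 times or more or reversed them, as for mitochondrially encoded (0.0185), triglyceride synthesis (0.0357), thermogenic (0.085) and fatty acid oxidation genes (0.0423) without the third control library and for heat shock genes (0.0123) without the first knockout library. Without each library in turn 15 of the 24 lists passed. Over all genes 0 members of the 24 passed, and fry called 0 lists.

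**Figure D2:**
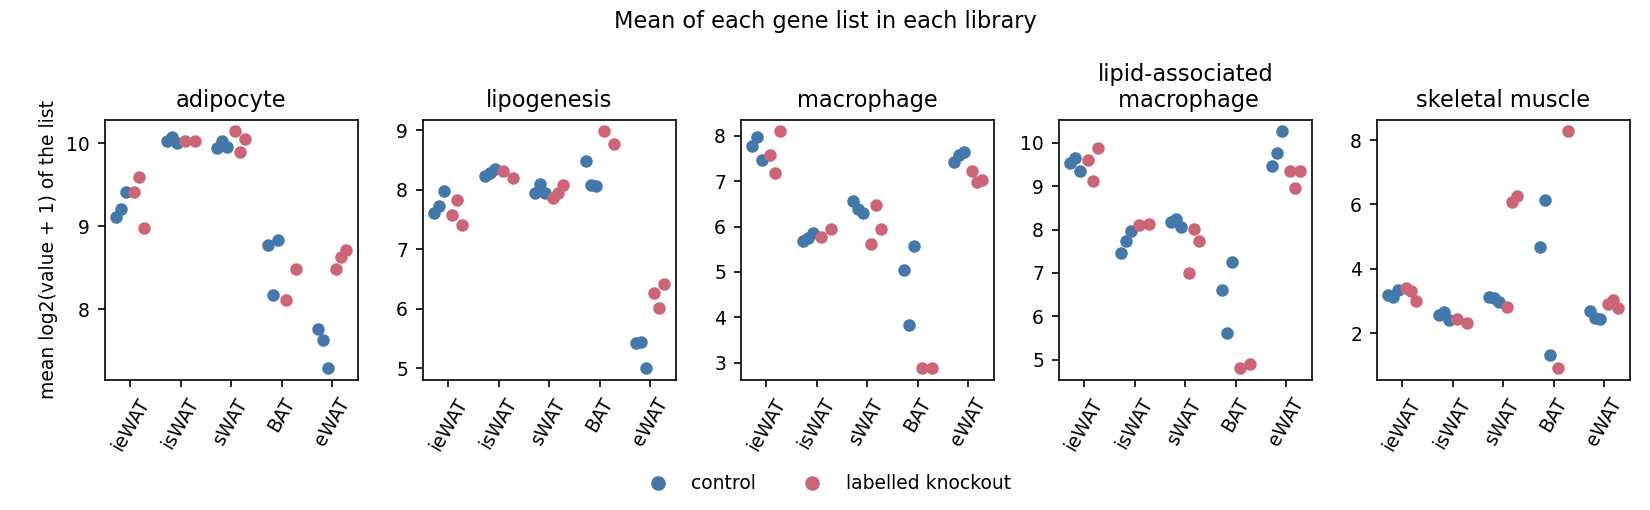
Mean log2(value + 1) of 5 gene lists in each library (points), control beside labelled knockout, for each depot on the horizontal axis. The skeletal muscle list stands at 6.06 and 6.26 in 2 sWAT knockout libraries and at 2.82 in the other, and the adipocyte list separates the eWAT groups (7.56 and 8.61 on average).

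The eWAT comparison set 3 control libraries against 3 labelled knockout, in which Fgf13 was not lower, so each direction follows the labels. Adipocyte genes rose. Adipoq, which encodes adiponectin, rose from 571 ± 143 to 1431 ± 122 FPKM (n = 3 each; log2 change 1.35, SE 0.20, limma adjusted p = 0.0128), and leptin, Lep, from 412 ± 99.1 to 1314 ± 236 FPKM (1.68, SE 0.22, 0.0122). The insulin-responsive glucose transporter Slc2a4 rose from 12.0 ± 2.83 to 30.2 ± 3.78 FPKM (limma adjusted p = 0.0122), Pparg from 49.1 ± 4.26 to 85.8 ± 8.43 FPKM (0.0122), Fasn from 147 ± 27.4 to 473 ± 172 FPKM (0.0235), and the caveolar genes Cav1 from 466 ± 109 to 1041 ± 82.3 FPKM (0.0149) and Cavin1 from 235 ± 35.7 to 461 ± 31.1 FPKM (0.0122). Ucp1 was not among the genes tested. The 10 protein-coding or small RNA genes with the largest rise were Snora57, Amhr2, Cd209d, Kcnh2, Igfals, Gsta4, the carbonic anhydrase Car3 (1112 ± 451 to 3745 ± 501 FPKM), the complement factor Cfd (134 ± 60.8 to 468 ± 40.3 FPKM), the hormone Retn (59.9 ± 29.1 to 253 ± 44.1 FPKM) and the Wnt antagonist Sfrp5 (42.7 ± 14.8 to 178 ± 54.2 FPKM). Of the 10 with the largest fall, 8 were immunoglobulin variable genes, among them Igkv6-15 (62.0 ± 45.4 to 1.30 ± 0.889 FPKM, log2 change -4.44, limma adjusted p = 0.0315), and the others were the mast cell proteases Cma1 (314 ± 92.6 to 47.8 ± 49.3 FPKM, 0.0497) and Tpsb2 (345 ± 131 to 51.4 ± 50.6 FPKM, 0.0494). The B cell and lymph node list did not pass in eWAT, and its groups overlapped. Its means were 6.551, 2.898 and 3.955 in control libraries and 2.81, 4.396 and 3.053 in those labelled knockout. Of 13736 genes limma with Benjamini-Hochberg adjustment called 2041, of which 1395 were higher and 646 lower, or 68.3% higher. An unadjusted p under 0.05 was found for 4650 genes. The count was 12 without the third library labelled knockout, 907 without the second and 1112 without the first, and 561 and 1139 without the second and the third control libraries. The second eWAT table gave 1 call, and limma with the replicate number as a block gave 0. The groups did not overlap for 41.2% of genes, where chance gives 10%.

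Of 42 lists in eWAT 21 passed with limma's camera, 14 higher and 7 lower. The adipocyte list averaged 7.56 ± 0.25 in control and 8.61 ± 0.12 in the libraries labelled knockout (n = 3 each, camera adjusted p = 1.51e-10, but adjusted p = 0.542 with an estimated correlation, at which 0 lists passed), and 17 of 21 members rose over all genes and 18 adjusted over the list alone. Lipogenesis (12 of 16 over all genes, 16 adjusted over the list alone), branched-chain amino acid catabolism (15 of 18, and 16), fatty acid oxidation (15 of 21, and 17), citric acid cycle (12 of 17, and 14), lipolysis (12 of 14, and 13), triglyceride synthesis (8 of 11, and 9), cholesterol synthesis (11 of 19, and 14) and caveolae (7 of 10, and 8) lists were higher (camera adjusted p from 2.31e-08 to 3.07e-04), with Scd1 rising from 969 ± 254 to 2374 ± 230 FPKM, Dgat2 from 444 ± 108 to 1154 ± 35.7 FPKM, Plin1 from 287 ± 59.4 to 643 ± 41.5 FPKM and Bckdhb from 16.1 ± 1.35 to 53.7 ± 6.92 FPKM. Adjusted over the list alone, 1 member each of the branched-chain amino acid, fatty acid oxidation, lipolysis and caveolae lists was lower, and the lipolysis member also over all genes. Nuclear oxidative phosphorylation genes were higher by 0.29 (3.41e-11), 16 of 71 over all genes and 23 adjusted over the list alone, and mitochondrially encoded genes by 0.61 (1.02e-04), 1 of 13 and 11. Endothelial genes averaged 4.44 ± 0.16 and 5.05 ± 0.21 (camera adjusted p = 1.80e-07), 13 of 19 over all genes and 15 adjusted over the list alone, with Gpihbp1, which carries lipoprotein lipase, rising from 70.3 ± 10.1 to 139 ± 19.3 FPKM. Macrophage genes averaged 7.54 ± 0.10 and 7.08 ± 0.13 (8.85e-05), with 8 of 18 lower over all genes, and 14 lower and 2 higher adjusted over the list alone. The complement genes C1qa and C1qc fell from 850 ± 20.8 to 561 ± 60.1 FPKM and from 913 ± 18.1 to 563 ± 54.4 FPKM, and the engulfment receptor Mertk from 16.0 ± 1.51 to 9.27 ± 0.802 FPKM. In the second eWAT table, whose columns correlate poorly, C1qa and C1qc were higher (log2 changes of 2.02 and 2.17) and Mertk stayed lower. The neutrophil and mast cell list was lower by 1.69 (camera adjusted p = 0.00620), 3 of 8 over all genes, with Kit falling from 15.4 ± 3.35 to 4.47 ± 2.13 FPKM. Lipid-associated macrophage (2 of 15 lower and 1 higher over all genes), T and NK cell, cell cycle, immediate early and ribosomal protein lists were also lower, and pericyte and thermogenic lists higher (camera adjusted p from 3.07e-04 to 0.0384). Leaving out 1 library shrank 5 of the 21 changes 1.5 times or more: mitochondrially encoded genes to 0.366, pericyte to 0.3415 and cell cycle to -0.1495 without the second library labelled knockout, lipid-associated macrophage to -0.403 without the third control library, and T and NK cell to -0.4865 without the first. Without each library in turn 19 of the 21 lists passed. Fry called 13 lists, 11 of them among the 21.

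The series title names ceramide and nutrient sensing, and lists for both were tested in each depot with limma's camera. The sphingolipid list passed in BAT, where it averaged 4.66 ± 0.24 (n = 3) and 4.23 ± 0.02 (n = 2; adjusted p = 0.0146, adjusted p = 0.764 with an estimated correlation) and Smpd3 averaged 3.93 ± 0.991 and 1.21 ± 0.660 CPM. The 5 BAT libraries had the same order by this list (4.668, 4.42 and 4.904 in control, 4.24 and 4.217 in knockout libraries) as by the macrophage list (5.04, 3.821 and 5.572, 2.882 and 2.878), which was lower by 1.93, so the call does not set sphingolipid genes apart from the cell types that were lower there. Without the second knockout library it did not pass in BAT (adjusted p = 0.141). It did not pass in ieWAT, isWAT, sWAT or eWAT (adjusted p = 0.343, 0.601, 0.350 and 0.269), though in eWAT 4 of 32 members were higher and 4 lower over all genes. The list of mTORC1 and AMPK nutrient sensing passed in BAT as higher (adjusted p = 0.00991, adjusted p = 0.576 with an estimated correlation), while its mean change was -0.01 and its median -0.02, so the signs differ, and it did not pass without the first knockout library (adjusted p = 0.0503). Camera ranks members against the other genes, whose median was -0.18. In ieWAT, isWAT, sWAT and eWAT it did not pass (adjusted p = 0.874, 0.673, 0.778 and 0.754). Whether the depots differ was not tested.

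Across depots, 3 genes were called higher by limma in at least 2 depots (Gm7049, Gm11868 and Bckdhb), and 1, Gm7049, in 3. In eWAT the log2 change of Bckdhb was 1.67 (SE 0.12, adjusted p = 0.00467) and that of Gm7049 3.94 (SE 0.16, adjusted p = 0.00104). In ieWAT and isWAT Bckdhb changed by 0.09 (SE 0.18) and 0.06 (SE 0.10). Gm7049, Gm11868, Morf4l1-ps1, Bckdhb and Gsta4, singled out after their values were seen, separated the groups in sWAT, BAT and eWAT and in neither inducible set. At an unadjusted p under 0.05, 4 genes were higher in 4 depots (Cdo1, Chpt1, Mpc1 and Rfc4) and 32 lower. Among the lower genes, Sgms1, which makes sphingomyelin from ceramide, had log2 changes of -0.40, -0.43, -0.35, -0.39 and -0.41 in ieWAT, isWAT, sWAT, BAT and eWAT, and the hexokinase Hk1 -0.53, -0.22, -0.29, -0.55 and -0.44; both were picked after their values were seen. At that threshold 432 genes were lower in both sWAT and eWAT, where independent lists would share 153 (one-sided Fisher's exact test, adjusted p = 1.70e-108 over 40 comparisons), and 121 higher, against 45.9. sWAT and BAT shared 392 lower genes against 179, and BAT and eWAT 693 against 326. In opposite directions, 2 comparisons passed an adjusted p of 0.05 by the same Fisher's test, while others exceeded the expected number without passing. The 2 were genes higher in ieWAT and lower in BAT (38 against 21.5, adjusted p = 5.14e-04) and genes lower in ieWAT and higher in sWAT (6 against 1.57, adjusted p = 0.0122). Fisher's test counts genes that move together, and depots that may share animals, as independent, so these p may be too small by an unknown amount. Between the inducible sets ieWAT and isWAT shared 43 lower genes against 8.22 and 20 higher against 7.16. Fewer ieWAT genes had an unadjusted p under 0.05 than that threshold would give without an effect. The subcutaneous sets isWAT and sWAT shared 0 calls by limma, and at the unadjusted threshold 221 lower genes against 99.0 and 26 higher against 10.1. The epididymal sets ieWAT and eWAT shared 0 calls, and 11 higher and 10 lower genes at the unadjusted threshold against 40.1 and 12.5. Across genes, which are not independent replicates, log2 changes correlated at 0.41 (sWAT and eWAT), 0.42 (sWAT and BAT), 0.07 (isWAT and sWAT) and -0.22 (ieWAT and eWAT). Each depot has its own control libraries, and no test of a difference between tables was made.

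**Figure D3:**
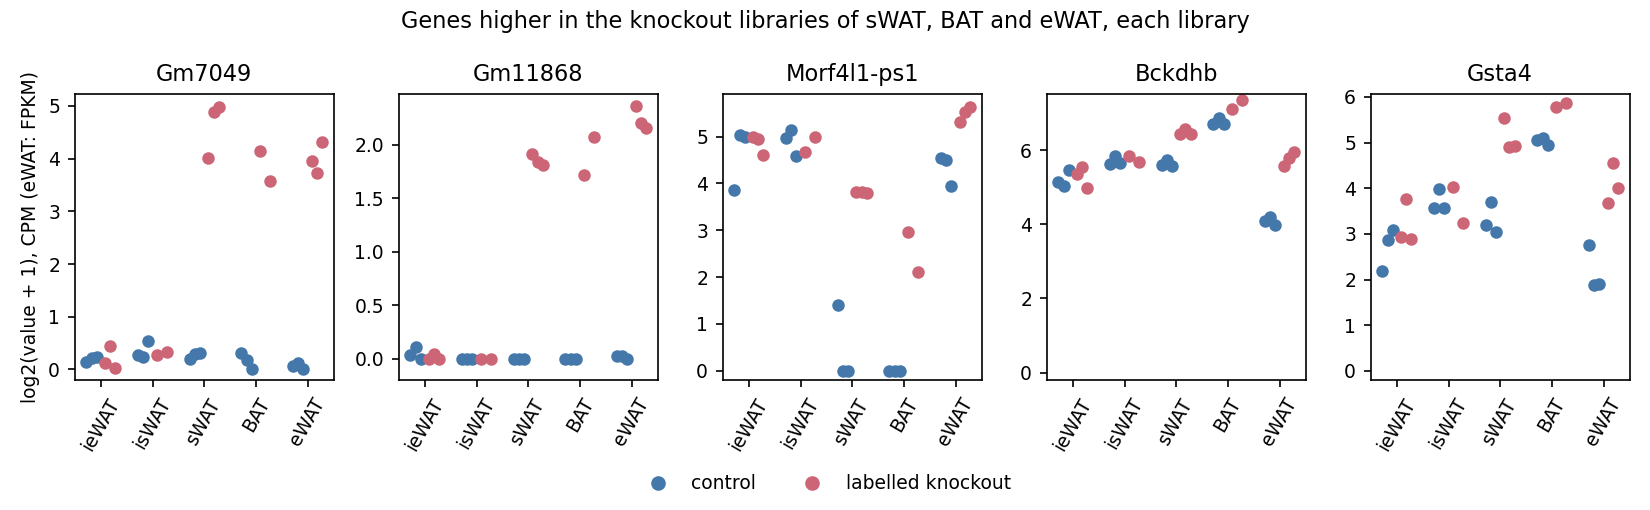
Gm7049, Gm11868, Morf4l1-ps1, Bckdhb and Gsta4 in each library (points) by depot and group. The groups are apart for 5 of 5 genes in sWAT, BAT and eWAT and for 0 of 5 in ieWAT and isWAT.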

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

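The tests of loss of Fgf13, of a chromosome segment, of the eWAT labels and of macrophage number were chosen only after the results they measure had been seen, as were the bounds of the first and the last, and the sWAT fits that allow for muscle RNA were added after the data had been examined.

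Some list means moved in opposite directions in different depots, each library of one group lying on one side of each library of the other. The lipid-associated macrophage list was higher in the isWAT knockout libraries by 0.39 (log2) and changed by -0.58 in sWAT, -1.63 in BAT and -0.62 in eWAT. The T and NK cell list was higher in ieWAT by 0.80 and changed by -0.85 in BAT. The endothelial list changed by -0.23 in isWAT and -0.26 in sWAT and was higher in eWAT by 0.61, where the direction follows labels that Fgf13 does not bear out. The depots were deposited as separate tables, and the differences between them were not tested.

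A value was also read in the second eWAT table, which holds the same 6 samples as the FPKM table and so gives no independent support. In the second eWAT table, Gm7049 averaged 6.17 TPM in the columns named knockout (2.10, 4.64 and 11.8) and stood at 0.0236, 0 and 0 TPM in those named control. That table separates its columns by Gm7049 in the same direction as the FPKM table.

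Gm7049, Gm11868, Morf4l1-ps1, Bckdhb and Gsta4 were higher in each knockout library of sWAT and BAT and each library labelled knockout of eWAT than in the control libraries. Loss of Fgf13, acting alike in each depot, would need a similar rise in ieWAT and isWAT, where Fgf13 was 38.9% and 44.8% lower, against 42.3% in sWAT. The median log2 change of the 5 genes there was 0.09 and -0.04, below the smallest median of the other depots, 1.85, by 1.76 and 1.90. The SE of these distances, 0.62 and 0.64, is that of each library's median level, not of the changes. The 5 genes were singled out after their values in each depot were seen, so a low median there does not decide it. Gm11868 was also listed at 0 in each isWAT library. Morf4l1-ps1 differed between the control libraries of the sets: 13.5 to 31.8 CPM in ieWAT and 23.2 to 34.1 CPM in isWAT, against 0 to 1.65 CPM in sWAT. In control libraries it was listed at 0 in BAT and at 14.3 to 22.4 FPKM in eWAT. The sets thus differed for this gene without knockout, for a cause not tested, so its missing rise in the inducible sets is hard to read. Bckdhb alone changed by 0.09 (SE 0.18) in ieWAT and 0.06 (SE 0.10) in isWAT, against 0.85 (SE 0.08) in sWAT and 0.48 (SE 0.12) in BAT. A small rise in ieWAT is not excluded. An effect that only constitutive loss has stays open for sWAT and BAT, since the type of knockout differs between these sets. In eWAT, whose knockout type is not stated, the median change was 1.89 although Fgf13 was not lower (log2 change 0.19, SE 0.28). The adipocyte list was higher in the same libraries by 1.05 (SE 0.16), and Fgf13 was read in whole tissue. An unchanged level in whole tissue does not show whether Fgf13 was lower within adipocytes. Whether a lower Fgf13 is the cause in eWAT therefore stays open. Reads shared with another gene may place the pseudogene signal: Gm7049 shares 65.3% of its 31-base words with Me1, Gm11868 57.9% with Cyb5r4 and Morf4l1-ps1 95.3% with Morf4l1, and these 3 partners lie on chromosome 9, as do Bckdhb and Gsta4. The partners' own log2 changes in sWAT, BAT and eWAT went both ways for Me1 (-0.47, -0.02 and 0.66) and were below 0 for Cyb5r4 (-0.29, -0.10 and -0.56) and Morf4l1 (-0.10, -0.22 and -0.13), so they do not settle it. A candidate explanation is therefore a chromosome 9 segment of another strain carried with the knockout line, whose altered transcripts would be assigned to pseudogenes. Against it as the source of the genes the 3 depots share, the 230 genes with the same direction did not crowd: the fullest window of 20 Mb held 8, against a median of 9 in random draws (permutation p = 0.94), and the 215 lower genes held 8 (permutation p = 0.85). The 15 higher genes held 2 at their own positions (permutation p = 0.86), but 5 on chromosome 9 once each pseudogene was placed at its closest partner (median of draws 2, permutation p = 0.0004). That placement was chosen after the partners were seen and the drawn genes were not placed again, so this p is too small by an unknown amount. A draw on the 5 genes alone was also run and is not used, because they were picked by eye. The 5 positions in the chromosome 9 window are Bckdhb, Gsta4, Me1, Cyb5r4 and Morf4l1, the same picked genes or their partners. The permutation p of 0.0004 therefore rests on them as well. A segment stays open for these 5 genes, and no genotype in the labels tests it.

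Oxidative phosphorylation lists were higher in the sWAT knockout libraries, of which the second and the third also held skeletal muscle transcripts (list means of 6.06 and 6.26, against 2.82 in the first and 2.97 to 3.13 in control). With the muscle list's mean as a covariate, 29.7% of the mean change of the nuclear list was left (0.05 before, with an SD of 0.07 between members, and 0.02 after, SD 0.10; camera adjusted p = 0.358) and 34.9% of that of the mitochondrially encoded list (0.42 before, SD 0.16, and 0.15 after, SD 0.25; camera adjusted p = 0.116). Muscle RNA in those libraries may thus account for most of both. The calls ended because the change shrank: the earlier change with the errors of the covariate fit still passed (adjusted p = 1.92e-05 and 4.26e-18), and the smaller change with the earlier errors did not (0.212 and 0.0691). Since both other knockout libraries hold the muscle RNA, what is left rests mainly on the first (0.01 and 0.11 in that library alone). An effect of knockout that varies with muscle content stays open, and no biological explanation was tested. In the same fit the lipid-associated macrophage list changed by -1.09 (camera adjusted p = 3.19e-10) and the branched-chain amino acid list by 0.31 (camera adjusted p = 1.09e-05), against -0.58 and 0.17 without the covariate. Both lean on the first knockout library: without it, and without the covariate, they were -0.289 and 0.0879 (camera adjusted p = 0.0147 and 0.0191). Neither list passed in the main fit with an estimated correlation (adjusted p = 0.778). The endothelial list changed by -0.11 (camera adjusted p = 0.401), against -0.26 without it.

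Many genes differed between the eWAT groups although Fgf13 did not. Exchanged labels would mix the groups for genes that mark the sWAT and BAT knockout libraries. Among genes tested in all 3 depots, 17 were higher in both (limma unadjusted p under 0.05), chosen without their eWAT changes. Of these, 15 separated the eWAT libraries by their labels, against at most 2 by another split, which argues against that. Of 392 genes lower in both, 217 separated the eWAT libraries in the same direction, against at most 29 by another split. Over all genes tested in eWAT, counting both directions, the groups did not overlap for 41.2%. Parting by the labels was thus common in eWAT, so the 217 say little about exchanged labels. Neither the 15 nor the 217 genes show that Fgf13 was deleted. Fewer macrophages in the libraries labelled knockout would raise the other cell types alike. The mean log2 change was 1.05 (SE 0.16) for the adipocyte list, 0.61 (SE 0.15) for the endothelial list and -0.21 (SE 0.08) for the fibroblast and progenitor list. The first and the last lie 1.26 apart (SE 0.16), which argues against a macrophage loss as the whole cause. A larger share of adipocytes, or a change within them, stays open and was not tested.

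The 3 against 3 comparisons allow 10 splits of the 6 libraries, too few for a share under 0.05. In ieWAT the real split gave 0 genes and the highest other split 0, so that 10 of 10 gave as many, and it gave 14 lists against 23 (5 of 10 gave as many). In sWAT the real split gave 3 genes and the highest other 1 (1 of 10), and 11 lists against 19 (4 of 10). In eWAT it gave 2041 genes against 3 (1 of 10) and 21 lists against 23 (2 of 10).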

How the results depend on the processing

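The fits with edgeR, DESeq2, the muscle covariate, without both muscle-rich libraries and on the second eWAT table were chosen after seeing the data. Fgf13 stayed below control in ieWAT, isWAT, sWAT and BAT under each setting run (log2 changes of -0.86 to -0.59, -0.92 to -0.73, -1.33 to -0.59 and -3.12 to -1.53). It passed its threshold with DESeq2 in isWAT (-0.83) and BAT (-2.85), and in sWAT with the covariate (-1.29) or without both muscle-rich libraries (-1.33). The last fit leaves 1 knockout library, the one with the lowest Fgf13, which was assumed to vary like control, and the covariate fit rests mainly on the same library, so neither adds to the evidence from 3. In eWAT leaving out 1 library gave -0.09 (without control 3) to 0.43, and 1.11 came from the second table, further from the main 0.19 than any other setting.

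Counts of genes past the threshold moved by over 1.5 times as follows, and the cause was not tested except where fewer libraries or a looser threshold is the change itself. At an unadjusted p under 0.05 the counts were 386 (ieWAT), 1869 (isWAT), 1334 (sWAT), 2540 (BAT) and 4650 (eWAT). DESeq2 called 32, 245, 85 and 691 in the first 4, and edgeR 0 in BAT. Without a filter on low values the counts were 3 (isWAT), 5 (sWAT), 7 (BAT) and 544 (eWAT), with more genes tested. A pseudocount of 0.1 gave 5 in sWAT and 0 in BAT, and eBayes without its options 0 in isWAT and 0 in BAT. In BAT quantile normalisation gave 2, median centring 9, a mean of at least 5 CPM 0 and array weights 2880; array weights gave 3858 in eWAT. In sWAT the covariate gave 169 and leaving out both muscle-rich libraries 681. In eWAT the second table gave 1, an adjusted p under 0.1 gave 3618, and a change of at least 2-fold 390.

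Leaving out each library in turn gave 0 to 1 genes in ieWAT, 0 to 12 in isWAT, 1 to 120 in sWAT, 0 to 2201 in BAT and 12 to 1819 in eWAT. Where this left 1 knockout library, it was assumed to vary like the control group. The 120 came without sWAT knockout 1, the 2201 without BAT control 2 and the 12 without eWAT library 3 labelled knockout.

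The groups share replicate numbers, but the labels do not say what a number marks, and same-numbered samples did not deviate together throughout: the pairing correlations were 0.109, 0.136 and -0.391 in ieWAT, -0.328 and -0.561 in isWAT, -0.242, 0.00326 and -0.141 in sWAT, -0.164 and 0.390 in BAT, and -0.243, -0.317 and 0.0634 in eWAT. Samples closest to their own number were 2 of 6, 0 of 5, 0 of 6, 2 of 5 and 0 of 6. With the replicate number as a block, limma called 1, 7, 1, 0 and 0 genes in ieWAT, isWAT, sWAT, BAT and eWAT, and edgeR with the block 1 in ieWAT, 0 in isWAT and 17 in BAT.

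Camera with an estimated correlation called 0 lists in each depot, against 14, 12, 11, 24 and 21. Fry, which asks whether the genes of a list move one way without comparing them with other genes, called 0 in ieWAT, isWAT, sWAT and BAT and 13 in eWAT. In sWAT the covariate gave 6 lists, 4 of them among the main 11, and leaving out both muscle-rich libraries 3, 2 of them among the 11. With the covariate the B cell (adjusted p = 0.222), interferon response (0.156), unfolded protein response (0.108) and endothelial (0.401) lists did not pass, besides skeletal muscle itself and both oxidative phosphorylation lists. The second eWAT table gave 13. Leaving out BAT knockout 2 turned the skeletal muscle list from higher to lower past the threshold.

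Genes shared between depots also moved with the threshold: isWAT and sWAT shared 0 calls, and 247 at an unadjusted p under 0.05; ieWAT and eWAT 0 and 21; and at least 3 depots 1 and 406, or 12 with DESeq2 calls.

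Among named genes past the threshold the sign changed in eWAT alone, and only with the second table, whose columns correlate poorly with one another (0.54 at the lowest): Ndufv3 -0.18, Cox8a -0.03, Cpt2 -0.14, Hibch -0.20, Dbt -0.12, C1qa 2.02, C1qb 1.5, C1qc 2.17, Cd9 1.12, Top2a 0.49, Klf2 0.54 and Dusp1 1.25. Of the other values of named genes under alternatives, 357 in eWAT kept their sign and lost the threshold, and 231 in BAT and 59 in sWAT kept their sign and passed it.

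The tests meant for count tables, fixed before the data were examined, were not the main tests, since no table held counts as deposited. edgeR was run only as an alternative, on the recovered reads of ieWAT, isWAT, sWAT and BAT. A single fit of all depots, also fixed before, was not run, since no table held more than 1 depot. Depth limits values near the floor: 1 read was worth up to 0.0741 CPM, and such limits cover counting error only.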

Other observations

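The test of Esr1 was chosen after its values had been seen. Esr1 was higher in each knockout library than in each control library of the inducible sets, ieWAT (11.7 ± 3.77 and 21.3 ± 4.28 CPM) and isWAT. A hypothesis is that part of these are reads from an inducible Cre fused to an estrogen receptor, although the labels do not name the method of induction. It predicts groups that are apart in ieWAT and isWAT and in no other depot, and they were apart in 2 depots, those 2. In ieWAT the lowest knockout library was 1.07 times the highest control library, and the group means were also higher in the libraries labelled knockout in sWAT (15.7 and 22.9 CPM), BAT (6.25 and 7.39 CPM) and eWAT (2.98 and 4.24 FPKM), so a higher native Esr1 may account for part of it.

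Rfc4, the gene next to Adipoq on chromosome 16, was singled out after its values were seen. Its log2 change was 0.65 in ieWAT, 0.85 in isWAT, 0.50 in sWAT, 0.23 in BAT and 0.55 in eWAT, and its groups overlapped in BAT alone. That of Adipoq itself was 0.12, 0.26, -0.06, -0.43 and 1.35. Eif4a2, beyond Rfc4, had 0.08, 0.14, 0.47, 0.51 and 0.50 in the same order, with groups apart in sWAT, BAT and eWAT alone. St6gal1, on the other side of Adipoq, had 0.04, -0.22, -0.43, -0.0009 and -0.57.

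Of 12148 genes tested in all 5 depots, 515 had a higher and 1582 a lower mean in each of the 5, or 17.3%. Independent signs that are equally likely in both directions would give 6.25%. The median change of all genes was -0.18 in BAT, -0.05 in sWAT, -0.03 in isWAT, -0.02 in eWAT and 0.02 in ieWAT. Depots may also share animals, so 6.25% is not a fair share to expect without an effect.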
